A study of Homo sapiens with 9 samples.

How the data were processed

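Gene expression was measured in GM12878, a human lymphoblastoid B-cell line made by Epstein-Barr virus transformation, on 9 Affymetrix Human Exon 1.0 ST arrays with 1 array per culture. Per the labels, cells were seeded at 900000 cells per ml in medium with 15% serum. They were exposed to 10 µM D,L-sulforaphane, an isothiocyanate, for 8 h or 24 h, or harvested untreated at 0 h, with 3 cultures per group. The treatment protocol also mentions a vehicle of 0.1% DMSO, but no array of vehicle-treated cells was used here, so the 0 h cultures are the only controls.

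The authors summarised the probes of each core transcript cluster with gene-level RMA and normalised the arrays with the sketch-quantile method in Affymetrix Expression Console. The deposited values are log2 RMA signals, 1 per transcript cluster and array. The versions of Expression Console and RMA, the annotation release and the genome build are not given in the sources used here. The table held 22011 clusters. Of these, 14432 carried a single gene symbol, 2408 carried several and 5171 had no gene in the annotation table. The single symbols covered 14232 distinct genes, and 197 symbols had more than 1 cluster. For such symbols the cluster with the highest mean over all arrays stood for the gene. All 22011 clusters were kept and tested, because control clusters could not be told from unannotated ones. Only clusters with a single symbol were named as genes. No positions are given, since the build is not known. Arrays give signal and not counts, and the number of arrays limits the precision. NQO1 and NFE2L2 had no cluster of their own and were not analysed here.

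The values were fitted with limma 3.58.1 in R 4.3.3 as deposited, with 1 mean per group and no further covariate. The 3 comparisons were 8 h against 0 h, 24 h against 0 h and 24 h against 8 h. Standard errors and two-sided moderated tests came from eBayes over all 9 arrays. P-values were adjusted by the Benjamini-Hochberg method over all clusters within a comparison, and a cluster was called at an adjusted p below 0.05. A moderated F-test over both comparisons with 0 h tested for any change among the 3 time points. From the 3 comparisons, clusters were classed as early transient, sustained or late. Early transient clusters were called at 8 h, not called at 24 h, and called in the opposite direction from 8 h to 24 h. Sustained clusters were called in the same direction at both times. Late clusters were called at 24 h, not called at 8 h, and called in the same direction from 8 h to 24 h.

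A total of 31 gene lists covered stress responses, the cell cycle, immune and metabolic functions, B-cell programmes and markers of other cell types. They were tested with camera at a preset inter-gene correlation of 0.01 over the 14232 named genes and adjusted over the lists within each comparison. The test was repeated with the correlation estimated from the data. The fry test was run as a second method; it asks whether the genes of a list move on balance in one direction, or change in either direction, and does not compare the list with other genes. Members called over all clusters were counted beside members called when the p-values were adjusted over the list alone. Genes were named by a rule. It took the 12 largest rises and the 12 largest falls among called genes at 8 h and at 24 h, and the 6 largest of each from 8 h to 24 h, where the arrays of both groups did not overlap. It also took up to 4 called members of each list, or the 2 with the smallest p where none was called, and a fixed panel of genes that includes HMOX1, GCLM, GCLC, TXNRD1, SRXN1, SLC7A11, KEAP1 and RXRA. The groups, comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined.

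Alternatives tried were a replicate block, leaving out the 25% of clusters with the lowest means, leaving out clusters below the median, quantile normalization, centring each array on its median, trended and robust eBayes, array weights, single-symbol clusters with the same symbol averaged, a stricter threshold of 0.01, a 1.5-fold minimum, fits of only the 2 groups compared, and leaving out each array in turn. Array weights fitted gene by gene, clusters with at least 1 symbol, list members counted without each array, both thresholds for single genes, leaving out clusters with 3 equal arrays in a group, and simulated unchanged groups with each group's own spread were added after seeing the data.

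The workflow was tested on simulated data. With 50 simulated clusters per fold change among 22011, the 8 h comparison called 42% of 1.5-fold changes, 80% of 2-fold changes and 98% of 4-fold changes. It made 4 false calls among 120. The 24 h comparison called 82% of 2.25-fold changes and made 10 false calls among 188, and the comparison of 24 h with 8 h made 6 among 125. A list of 27 members shifted by 0.5 on the log2 scale was called, and 0 of the other 30 lists were. The simulated noise was independent between clusters, with the same spread in all groups. False list calls that come from correlated genes could therefore not appear. In the data the estimated correlation within the mitosis list was 0.348. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.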

Results

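The data were 9 arrays from GM12878 lymphoblastoid cells. They comprised 3 untreated cultures at 0 h, 3 cultures after 8 h of 10 µM sulforaphane and 3 after 24 h. No array came from cells kept for 8 or 24 h without sulforaphane, so time in culture and treatment changed together in every comparison. Values were log2 signals of 22011 transcript clusters, and the mean signal per array lay between 7.97 and 8.14. The median correlation between arrays was 0.992 within groups and 0.989 between groups. Untreated replicate 2 stood apart from the other arrays, with a first-component score of 54.4 against -29.9 for 24 h replicate 1 at the other end. Its upper-quartile signal was 9.28, against 9.54 and 9.49 on the other untreated arrays. The median standard deviation of a cluster was 0.150 among untreated arrays, 0.0912 at 8 h and 0.0919 at 24 h. Changes below are log2 differences with standard errors, each with n = 3 arrays per group.

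**Figure D1:**
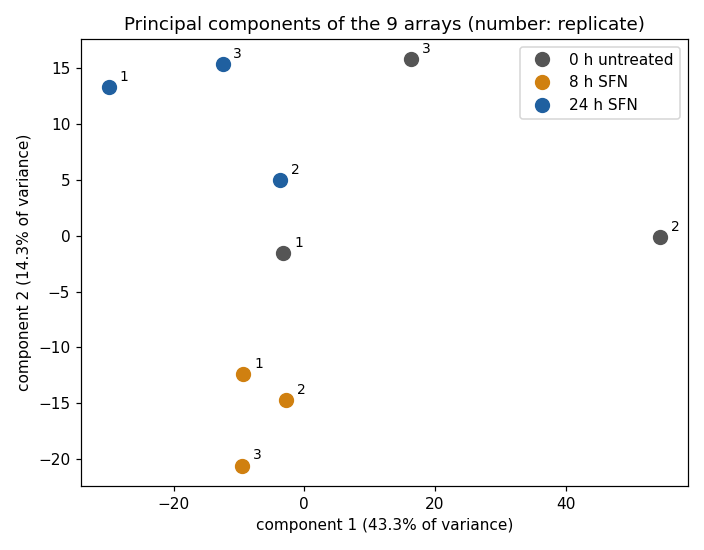
Scores of the 9 arrays on the first and second principal components of all clusters, which hold 43.3% and 14.3% of the variance; each point is 1 array, coloured by group. Untreated replicate 2 has a first-component score of 54.4, and the 8 h and 24 h arrays lie apart on the second component.

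The comparison of 8 h with 0 h asked which genes had changed after 8 h of sulforaphane, a compound known to release the transcription factor NRF2 from its repressor KEAP1. HMOX1, the enzyme that breaks down haem (cluster 3944129), rose most. Its signal went from 8.93 ± 0.14 (SD, n = 3) to 12.36 ± 0.08, a change of 3.43 ± 0.09 (SE) or 10.8-fold (adjusted p = 3.5e-06). FTL, the light chain of the iron store ferritin (cluster 3838094), rose by 2.42 ± 0.10 or 5.35-fold (adjusted p = 0.00011). Chaperone genes rose beside them: HSPH1 by 0.98 ± 0.09 (adjusted p = 0.0066) and the co-chaperone DNAJB1 by 0.76 ± 0.09 (adjusted p = 0.017). The largest falls were in CCL20, a chemokine, which fell by 1.46 ± 0.21 (adjusted p = 0.031), and GPR84, a receptor for medium-chain fatty acids, which fell by 1.40 ± 0.07 (adjusted p = 0.00020).

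Other large rises at 8 h were ABCA9, a transporter of the ABC family (1.44 ± 0.17), TXK, a tyrosine kinase of the Tec family (1.33 ± 0.15), TEX12, a protein of the synaptonemal complex (0.86 ± 0.08), ABHD4, a lipase (0.84 ± 0.14), TNFRSF10D, a decoy receptor for the death ligand TRAIL (0.79 ± 0.13), and CFAP70, a ciliary protein (0.78 ± 0.09). TNFSF10, which encodes TRAIL itself, fell by 0.98 ± 0.16. CCNE2, a cyclin of S-phase entry, fell by 1.17 ± 0.15, and CDC6, which licenses replication origins, fell by 1.03 ± 0.13. FSTL3, a secreted inhibitor of activins, fell by 1.10 ± 0.13, FAM111B by 1.07 ± 0.15, and SGK1, a kinase induced by serum and glucocorticoids, by 1.07 ± 0.17. GATM, an enzyme of creatine synthesis, fell by 1.00 ± 0.11, CYRIA, a regulator of actin, by 0.97 ± 0.16, the ETS factor ETV5 by 0.92 ± 0.14, and IER3, an immediate early gene, by 0.90 ± 0.07. Of clusters without a single symbol, 3375648 rose by 1.78 ± 0.16 and 3374934 fell by 0.85 ± 0.11. Cluster 3696666, with 2 symbols, rose by 1.51 ± 0.09 (adjusted p = 0.00051).

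Of 27 measured NRF2 targets, 4 rose at 8 h, 0 fell and 23 did not pass, and 10 rose when adjusted over the list alone. The 4 were HMOX1, FTL, TXNRD1, which reduces thioredoxin (0.84 ± 0.11, adjusted p = 0.022), and PIR, a nuclear iron-binding protein (0.84 ± 0.08, adjusted p = 0.0066). The 4 became 7 without untreated replicate 1, 6 without untreated replicate 2 and 2 without untreated replicate 3. TXNRD1 did not pass in 6 of the fits without 1 array, and PIR in 1. The list as a whole was higher by a mean of 0.51 and a median of 0.23 (adjusted p = 4.4e-12, and adjusted p = 0.16 with an estimated correlation). HMOX1 and FTL also made up the 2 rises among 15 genes of haem and iron handling, where 3 rose and 1 fell adjusted over the list alone (adjusted p = 0.00039, and adjusted p = 0.22 with an estimated correlation). The haem list had a mean of 0.45 and a median of 0.085. Of 19 heat shock genes, 5 rose, 0 fell and 14 did not pass, and 10 rose when adjusted over the list alone. They included HSPH1, DNAJB1, HSP90AA1, a cytosolic chaperone (0.65 ± 0.09, adjusted p = 0.026), and BAG3, a co-chaperone of HSP70 (0.48 ± 0.06, adjusted p = 0.021). The list test gave adjusted p = 4.0e-14, and adjusted p = 0.16 with an estimated correlation. The heat shock count was 5 without untreated replicate 2, 8 without untreated replicate 1, 0 without untreated replicate 3, 1 without 8 h replicate 1 or 3, 3 without 24 h replicate 1 or 3, and 2 without 24 h replicate 2.

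Among 19 p53 targets, 1 rose at 8 h, BAX, an effector of apoptosis (0.43 ± 0.06, adjusted p = 0.023), and 7 rose when adjusted over the list alone. The 3 arrays of BAX at 24 h shared the value 11.24. The p53 count was 1 without untreated replicate 2, 4 without untreated replicate 1, and 0 without untreated replicate 3, 8 h replicate 1 or 3, or any 24 h array. The list was higher (adjusted p = 3.8e-09, and adjusted p = 0.19 with an estimated correlation). Among 15 autophagy and lysosome genes, 1 rose, MAP1LC3B, a protein of autophagosome membranes (0.60 ± 0.08, adjusted p = 0.019), and 2 rose when adjusted over the list alone (list adjusted p = 3.6e-06, and adjusted p = 0.19 with an estimated correlation). MAP1LC3B did not pass without untreated replicate 3, 8 h replicate 1 or 3, or 24 h replicate 2 or 3. None of 24 proteasome subunits was called, and the list had a mean of 0.06 (adjusted p = 0.035, and adjusted p = 0.70 with an estimated correlation). That mean was -0.016 without untreated replicate 2 (adjusted p = 0.45), and the list was not called without 8 h replicate 1 (adjusted p = 0.096) or 3 (adjusted p = 0.12) either.

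Of 25 DNA replication and G1/S genes, 2 fell at 8 h, CCNE2 and CDC6, and 19 fell when adjusted over the list alone. The list mean was -0.48 (adjusted p = 4.0e-14, and adjusted p = 0.19 with an estimated correlation). The number of fallen members was 10 without untreated replicate 2, 1 without 24 h replicate 3, and 0 without untreated replicate 3, any 8 h array or 24 h replicate 2. Of 25 interferon response genes, 3 fell: OAS1 (-0.64 ± 0.08, adjusted p = 0.019), OAS2 (-0.63 ± 0.10, adjusted p = 0.042) and OAS3 (-0.58 ± 0.07, adjusted p = 0.018), which make the second messenger that activates RNase L. Adjusted over the list alone, 13 fell and 1 rose (list adjusted p = 1.7e-05, and adjusted p = 0.32 with an estimated correlation). The 3 fallen members became 6 without untreated replicate 2, 1 without 8 h replicate 3 or 24 h replicate 3, and 0 without untreated replicate 3, 8 h replicate 1 or 24 h replicate 2. Of 15 immediate early genes, 1 fell, the transcription factor EGR1 (-0.51 ± 0.08, adjusted p = 0.048), and 5 fell when adjusted over the list alone (list adjusted p = 0.00018, and adjusted p = 0.19 with an estimated correlation). The number called over all clusters was 4 without untreated replicate 1, 1 without untreated replicate 2 and 0 without each of the other arrays. None of 16 cholesterol genes was called and 3 fell when adjusted over the list alone (list adjusted p = 0.036, and adjusted p = 0.70 with an estimated correlation). The cholesterol list was not called without untreated replicate 1 (adjusted p = 0.45), untreated replicate 3 (adjusted p = 0.099) or 8 h replicate 2 (adjusted p = 0.071). Myeloid markers also had a lower mean, -0.22, with 0 of 11 members called and 3 lower when adjusted over the list alone (adjusted p = 0.0055, and adjusted p = 0.27 with an estimated correlation).

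In lists that were not called at 8 h, HSPA5, the main chaperone of the endoplasmic reticulum, fell by 0.62 ± 0.08 (adjusted p = 0.018), as 1 of 18 genes of that list. In the same list 6 fell when adjusted over the list alone, and 3 fell over all clusters without untreated replicate 2. Among 18 NF-kB targets, IER3 and TNFAIP2 (-0.75 ± 0.08, adjusted p = 0.011) fell. Among 22 hypoxia and glycolysis genes, PFKFB3, which makes an activator of glycolysis (-0.48 ± 0.06), and ENO2, an enolase (-0.41 ± 0.06), fell. THY1, a surface protein in the fibroblast list, fell by 0.51 ± 0.07. IER3 passed without each array in turn, TNFAIP2 did not without untreated replicate 3 or 8 h replicate 1, and HSPA5, PFKFB3, ENO2 and THY1 did not without untreated replicate 3 or 8 h replicate 1 or 3. HSPA5 also failed without 24 h replicate 2, THY1 without 24 h replicate 2 or 3, and ENO2 without 8 h replicate 2 or any 24 h array. Without untreated replicate 2 the reticulum, NF-kB and hypoxia lists were called, as was the NF-kB list without 8 h replicate 1.

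In total, 131 clusters were called at 8 h against 0 h with limma. Of these, 59 rose and 72 fell, 18 by at least 2-fold, and 92 carried a single symbol. In each of the 131 the 3 treated arrays lay on one side of the 3 untreated arrays. A call largely implies such separation, here and in the other comparisons, so it is not further evidence. Of all clusters, 17.6% were separated in this way, against 10% by chance. Without untreated replicate 2, the array that stood apart, 291 were called, 76 up and 215 down. Without untreated replicate 1, 654 were called, 476 up and 178 down, so the balance of rises and falls depended on the arrays in the fit. Other counts were 9 without untreated replicate 3, 21, 83 and 27 without 8 h replicates 1, 2 and 3, and 76, 43 and 58 without 24 h replicates 1, 2 and 3. The 24 h arrays enter this comparison only through the shared spread, here and for its genes and lists. Of 37 called gene results named by the rule, 37, 35 and 4 passed without untreated replicates 1, 2 and 3, 8, 25 and 10 without 8 h replicates 1, 2 and 3, 23, 15 and 19 without 24 h replicates 1, 2 and 3, and HMOX1, FTL and GPR84 passed under every alternative.

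**Figure D2:**
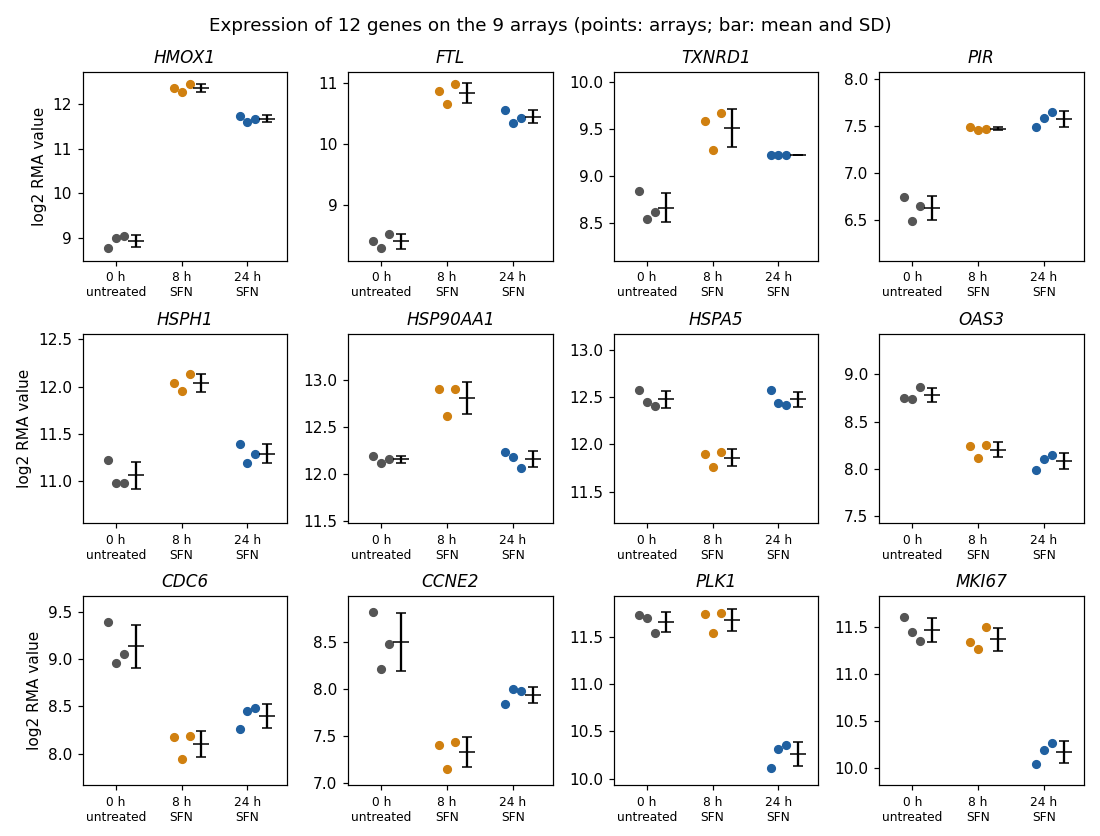
Log2 signal of 12 genes at 0, 8 and 24 h; points are single arrays and bars are the mean ± SD of 3 arrays. HMOX1 goes from 8.93 to 12.36 and 11.67, while PLK1 is 11.66 and 11.68 at 0 and 8 h and 10.26 at 24 h.

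The comparison of 24 h with 0 h asked which genes had changed after a day of sulforaphane. HMOX1 was 6.67-fold higher (2.74 ± 0.09, adjusted p = 2.1e-05) and FTL 4.08-fold higher (2.03 ± 0.10, adjusted p = 0.00030). ME1, malic enzyme, which makes NADPH, rose by 1.64 ± 0.31 (adjusted p = 0.048), and GCLC, the catalytic subunit of the first enzyme of glutathione synthesis, by 0.94 ± 0.18 (adjusted p = 0.047). Genes of mitosis were lower: PLK1, a mitotic kinase (cluster 3653072), fell by 1.40 ± 0.10 or 2.63-fold (adjusted p = 0.0014), AURKB, the kinase of the chromosomal passenger complex, by 1.34 ± 0.09 (adjusted p = 0.0014), and the proliferation marker MKI67 by 1.29 ± 0.10 (adjusted p = 0.0020). CDC20, an activator of the anaphase-promoting complex, fell by 1.47 ± 0.15 (adjusted p = 0.0086).

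Other large rises at 24 h were AGBL3, a carboxypeptidase (1.20 ± 0.21), YPEL5 (1.17 ± 0.16), TAS2R5, a bitter taste receptor (1.17 ± 0.19), KLHL24, a substrate adaptor of a ubiquitin ligase (1.17 ± 0.19), TXK (1.06 ± 0.15), PIR (0.94 ± 0.08), DSC3, a desmosomal cadherin (0.85 ± 0.14), and TCP11L2 (0.84 ± 0.12). Other large falls were CDCA3, a mitotic entry factor (-1.24 ± 0.10), the kinase PBK (-1.18 ± 0.18), the linker histone H1-5 (-1.16 ± 0.16), DLGAP5, a spindle protein (-1.16 ± 0.13), SGK1 (-1.12 ± 0.17), MYBL2, a transcription factor of cycling cells (-1.11 ± 0.12), KNL1, a kinetochore scaffold (-1.10 ± 0.10), and CDK1, the kinase of mitotic entry (-1.09 ± 0.18). Of clusters without a single symbol, 3696666 rose by 2.08 ± 0.09 and 3392880 fell by 2.05 ± 0.38.

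Of 27 mitosis and G2/M genes, 18 fell at 24 h, 0 rose and 9 did not pass, and 22 fell when adjusted over the list alone. The list mean was -0.85 (adjusted p = 7.1e-26, and adjusted p = 0.25 with an estimated correlation). The number of fallen members was 20 without untreated replicate 2, 5 without untreated replicate 3, 10 and 11 without 8 h replicates 1 and 3, and 7, 6 and 8 without 24 h replicates 1, 2 and 3. Of 25 DNA replication genes, 6 fell and 19 did not pass, and 18 fell when adjusted over the list alone (list adjusted p = 7.3e-13, and adjusted p = 0.27 with an estimated correlation). They included RRM2, a subunit of ribonucleotide reductase (-0.99 ± 0.14, adjusted p = 0.023), GINS1 (-0.77 ± 0.12, adjusted p = 0.027) and CDC45 (-0.73 ± 0.10, adjusted p = 0.021) of the replicative helicase, and CDC6 (-0.74 ± 0.13, adjusted p = 0.038). The 6 fallen members became 10 without untreated replicate 2, 1 without 8 h replicate 1 or 24 h replicate 3, and 0 without untreated replicate 3 or 24 h replicate 1 or 2. Of 29 replication-dependent histone genes, 6 fell, among them H1-5, H3C1 (-0.99 ± 0.15, adjusted p = 0.026), H2AC16 (-0.97 ± 0.13, adjusted p = 0.019) and H1-3 (-0.71 ± 0.11, adjusted p = 0.028), and 16 fell when adjusted over the list alone (list adjusted p = 6.3e-10, and adjusted p = 0.31 with an estimated correlation). The histone count was 6 without untreated replicate 2, 2 without 8 h replicate 3, 1 without 24 h replicate 1 or 3, and 0 without untreated replicate 3, 8 h replicate 1 or 24 h replicate 2.

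Of 27 NRF2 targets, 6 rose at 24 h, 0 fell and 21 did not pass, and 10 rose when adjusted over the list alone. The 6 were HMOX1, FTL, ME1, PIR, GCLC and SLC48A1, a haem transporter (0.64 ± 0.08, adjusted p = 0.015). The list mean was 0.53 and the median 0.25 (adjusted p = 6.3e-10, and adjusted p = 0.25 with an estimated correlation). The 6 risen members became 5 without untreated replicate 2 and 3 without untreated replicate 3 or 24 h replicate 2 or 3. GCLC did not pass in 8 of the fits without 1 array, and SLC48A1 in 3. HMOX1, FTL and SLC48A1 were the 3 rises among 15 haem and iron genes, with 5 adjusted over the list alone (list adjusted p = 1.2e-05, and adjusted p = 0.25 with an estimated correlation). The haem list had a mean of 0.52 and a median of 0.26. ME1 was the 1 rise among 7 pentose phosphate and NADPH genes (list adjusted p = 0.048, and adjusted p = 0.52 with an estimated correlation), where 1 rose adjusted over the list alone. Of the fits without 1 array, ME1 passed only in those without untreated replicate 1 or 2, and the list was not called without untreated replicate 2, 8 h replicate 2 or 3, or 24 h replicate 1. MGST1, a membrane-bound glutathione transferase (0.58 ± 0.10, adjusted p = 0.041), was the 1 rise among 23 other antioxidant enzymes, also 1 adjusted over the list alone (list adjusted p = 0.015, and adjusted p = 0.52 with an estimated correlation). Of the fits without 1 array, MGST1 passed only in that without untreated replicate 1.

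Of 19 p53 targets, 1 rose at 24 h, TP53INP1 (0.59 ± 0.08, adjusted p = 0.018), and 16 rose when adjusted over the list alone (list adjusted p = 6.9e-09, and adjusted p = 0.25 with an estimated correlation). The number called over all clusters was 1 without untreated replicate 2, 4 without untreated replicate 1, and 0 without untreated replicate 3, 8 h replicate 1 or any 24 h array. MAP1LC3B rose by 0.43 ± 0.08 (adjusted p = 0.039), the 1 rise among 15 autophagy genes (list adjusted p = 0.00072, and adjusted p = 0.31 with an estimated correlation). Of the fits without 1 array, it passed only in those without untreated replicate 1 or 8 h replicate 2. DNAJB9, a co-chaperone of the endoplasmic reticulum, rose by 0.50 ± 0.09 (adjusted p = 0.047), the 1 rise among 18 genes of that list, with 2 adjusted over the list alone (list adjusted p = 0.032, and adjusted p = 0.52 with an estimated correlation). DNAJB9 did not pass whichever array was left out, and the list was not called without untreated replicate 2 or 3 or 24 h replicate 1. None of 13 BCL2 family genes and none of 21 respiratory chain genes was called. The BCL2 family had 3 rises adjusted over the list alone (list adjusted p = 0.032, and adjusted p = 0.52 with an estimated correlation), and the respiratory chain had 0 (list adjusted p = 0.048, and adjusted p = 0.52 with an estimated correlation). The BCL2 list was not called without untreated replicate 1 or 24 h replicate 2, and had 1 member called without 8 h replicate 2. The respiratory chain list was not called without untreated replicate 2, 8 h replicate 2 or any 24 h array. Of 19 heat shock genes none was called at 24 h (list adjusted p = 0.067). The heat shock list was called without untreated replicate 1, 8 h replicate 2 or 24 h replicate 3, with 1 member called without untreated replicate 1.

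Of 25 interferon genes, 2 fell at 24 h, OAS3 (-0.70 ± 0.07, adjusted p = 0.0087) and XAF1 (-0.73 ± 0.14, adjusted p = 0.046), and 5 fell and 1 rose adjusted over the list alone (list adjusted p = 0.014, and adjusted p = 0.52 with an estimated correlation). The number called over all clusters was 4 without 8 h replicate 2, 0 without untreated replicate 3 and 1 without each of the other arrays, and the list was not called without untreated replicate 1 (adjusted p = 0.095). Of 15 immediate early genes, 2 fell, EGR1 (-0.44 ± 0.08, adjusted p = 0.048) and KLF6 (-0.44 ± 0.08, adjusted p = 0.043), and 4 fell adjusted over the list alone (list adjusted p = 0.015, and adjusted p = 0.31 with an estimated correlation). Without untreated replicate 2 only EGR1 passed, without 8 h replicate 2 only KLF6, and without each of the other arrays neither did, and the list was not called without 24 h replicate 2 (adjusted p = 0.051). DHCR7, which makes the last step of cholesterol synthesis, fell by 0.61 ± 0.08 (adjusted p = 0.017), the 1 fall among 16 cholesterol genes, with 4 falls and 1 rise adjusted over the list alone (list adjusted p = 0.022, and adjusted p = 0.53 with an estimated correlation). The number called over all clusters was 2 without untreated replicate 2 and 0 without untreated replicate 3, 8 h replicate 1 or any 24 h array, and the list was not called without untreated replicate 1 or 24 h replicate 2. Myeloid markers had a mean of -0.18 with 0 of 11 members called (adjusted p = 0.0086, and adjusted p = 0.31 with an estimated correlation). In lists that were not called, SLC7A5, an amino acid transporter (-0.39 ± 0.07), WARS1, a tRNA synthetase (-0.35 ± 0.06), and DNMT1, the maintenance DNA methyltransferase (-0.49 ± 0.09), fell, and BLK, a B-cell tyrosine kinase, rose by 0.44 ± 0.08. BLK did not pass whichever array was left out. Of the fits without 1 array, DNMT1 passed only in that without 8 h replicate 2, SLC7A5 in those without untreated replicate 1 or 8 h replicate 2, and WARS1 in those without untreated replicate 1 or 2 or 8 h replicate 2.

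In total, 357 clusters were called at 24 h against 0 h, 183 up and 174 down, 46 by at least 2-fold, and 248 carried a single symbol. All 357 had groups that did not overlap, as did 24.3% of all clusters, against 10% by chance. The share of calls that were rises, 51.3%, was 38.6% after quantile normalization (216 up and 344 down) and 40.0% after centring each array on its median (204 up and 306 down), as the number of falls grew by more than that of rises. Without untreated replicate 2, 314 were called, 98 up and 216 down, and without untreated replicate 1, 768 were called, 550 up and 218 down. Other counts were 21 without untreated replicate 3, 56 and 101 without 8 h replicates 1 and 3, and 44, 34 and 55 without 24 h replicates 1, 2 and 3. Of 45 called gene results named by the rule, 39, 32 and 8 passed without untreated replicates 1, 2 and 3, 13, 37 and 20 without 8 h replicates 1, 2 and 3, 15, 12 and 13 without 24 h replicates 1, 2 and 3, and HMOX1, FTL, PLK1, AURKB, MKI67 and CDCA3 passed under every alternative.

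**Figure D3:**
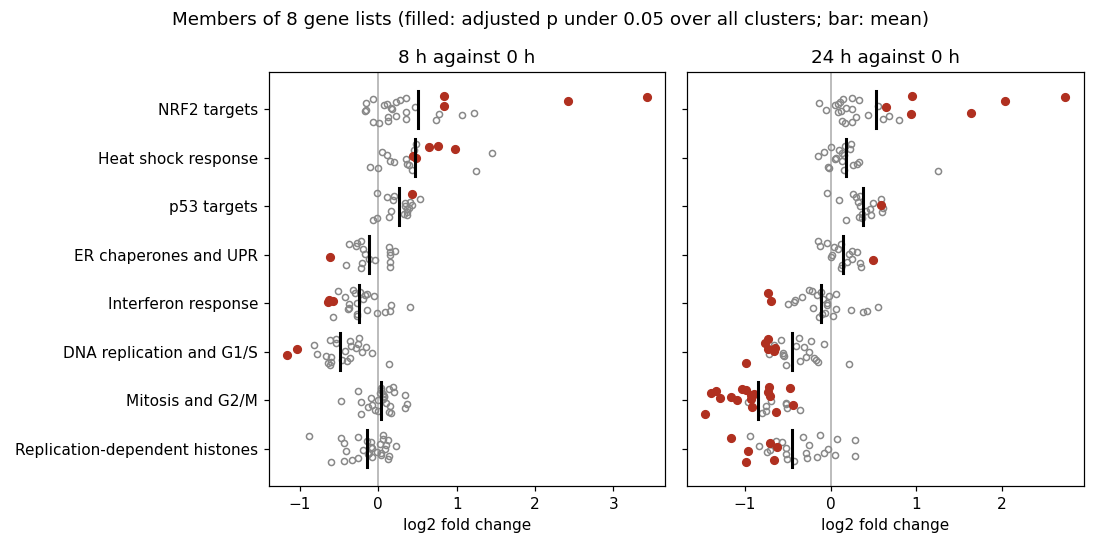
Log2 fold change of the members of 8 gene lists at 8 h and at 24 h against 0 h; points are genes, filled where the adjusted p is below 0.05, and bars are list means. The mitosis list has a mean of 0.03 at 8 h and -0.85 at 24 h, and the heat shock list 0.47 and 0.17.

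The comparison of 24 h with 8 h tested directly whether signals differed between the times, with exposure and time in culture changing together. Mitotic genes fell between 8 h and 24 h, led by PLK1 (-1.42 ± 0.10, adjusted p = 0.0025), CCNB2, a mitotic cyclin (-1.27 ± 0.14, adjusted p = 0.017), CDC20 (-1.24 ± 0.15, adjusted p = 0.022), DLGAP5 (-1.22 ± 0.13, adjusted p = 0.011), MKI67 (-1.20 ± 0.10, adjusted p = 0.0061) and TPX2, a spindle assembly factor (-1.17 ± 0.07, adjusted p = 0.0025). HMOX1 was lower at 24 h than at 8 h by -0.69 ± 0.09 (adjusted p = 0.026), and this difference passed without untreated replicate 1 or 2 but not without each of the other arrays. The largest rises were in KCND2, a potassium channel (1.24 ± 0.17, adjusted p = 0.034), and INA, a neuronal intermediate filament protein (1.11 ± 0.11, adjusted p = 0.0091), whose 3 untreated arrays shared the value 8.18. GATM (0.80 ± 0.11), DSG1, a desmosomal cadherin (0.66 ± 0.10), HSPA5 (0.62 ± 0.08) and COQ10A, a coenzyme Q-binding protein (0.58 ± 0.09), also rose.

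Of 27 mitosis genes, 13 fell from 8 h to 24 h, 0 rose and 14 did not pass, and 25 fell when adjusted over the list alone. The list mean was -0.89 (adjusted p = 1.5e-52, and adjusted p = 0.047 with an estimated correlation), the 1 list call that held with an estimated correlation in any comparison. The 13 fallen members became 19 without untreated replicate 2, 3 and 6 without 8 h replicates 1 and 3, and 6, 5 and 7 without 24 h replicates 1, 2 and 3. Of 19 heat shock genes, 4 fell: HSPH1 (-0.75 ± 0.09, adjusted p = 0.025), HSP90AA1 (-0.64 ± 0.09, adjusted p = 0.039), STIP1, a link between HSP70 and HSP90 (-0.59 ± 0.05, adjusted p = 0.0072), and BAG3 (-0.43 ± 0.06, adjusted p = 0.049). Adjusted over the list alone, 8 fell (list adjusted p = 6.1e-11, and adjusted p = 0.24 with an estimated correlation). The 4 fallen members became 5 without untreated replicate 2, 2 without untreated replicate 1, 1 without untreated replicate 3 or 24 h replicate 1 or 3, and 0 without 8 h replicate 1 or 3 or 24 h replicate 2. Of 18 genes of the endoplasmic reticulum list, 3 rose, HSPA5 (adjusted p = 0.025), MANF, a secreted stress protein (0.54 ± 0.08, adjusted p = 0.049), and HYOU1, a chaperone (0.38 ± 0.05, adjusted p = 0.038), and 8 rose when adjusted over the list alone (list adjusted p = 1.0e-05, and adjusted p = 0.42 with an estimated correlation). The 3 risen members became 4 without untreated replicate 2, 1 without untreated replicate 1, and 0 without untreated replicate 3 or any 8 h or 24 h array.

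None of 29 histone genes was called from 8 h to 24 h and 13 fell when adjusted over the list alone (list mean -0.31, adjusted p = 2.5e-13, and adjusted p = 0.31 with an estimated correlation). IER3 rose by 0.58 ± 0.07 (adjusted p = 0.025), the 1 rise among 18 NF-kB targets, with 3 adjusted over the list alone (list adjusted p = 5.0e-05, and adjusted p = 0.29 with an estimated correlation). It did not pass without any 8 h or 24 h array. PHGDH, the first enzyme of serine synthesis, fell by 0.50 ± 0.07 (adjusted p = 0.043), the 1 fall among 27 ATF4 and amino acid genes, with 2 adjusted over the list alone (list adjusted p = 0.0050, and adjusted p = 0.61 with an estimated correlation). Of the fits without 1 array, PHGDH passed only in that without untreated replicate 2, and the list was not called without 8 h replicate 1 (adjusted p = 0.053). TM7SF2, a sterol reductase in a list that was not called, rose by 0.40 ± 0.05, and passed without untreated replicate 1 or 2 but not without each of the other arrays. In total 72 clusters were called, 22 up and 50 down, and 52 carried a single symbol. With array weights more clusters rose than fell, 915 against 601, and with weights fitted gene by gene 845 against 480. All 72 had groups that did not overlap, as did 21.6% of all clusters, against 10% by chance. Without untreated replicate 2, 160 were called, 73 up and 87 down. Other counts were 30 without untreated replicate 3, 4, 46 and 10 without 8 h replicates 1, 2 and 3, and 16, 11 and 18 without 24 h replicates 1, 2 and 3. Of 22 called gene results named by the rule, 13, 22 and 9 passed without untreated replicates 1, 2 and 3, 2, 11 and 4 without 8 h replicates 1, 2 and 3, 5, 4 and 5 without 24 h replicates 1, 2 and 3, and PLK1 and TPX2 passed under every alternative.

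Over the time course, 298 clusters changed among the 3 time points by the F-test. The early transient class held 11 clusters, 6 up and 5 down, with HSPH1, HSP90AA1, STIP1 and BAG3 among the rises and HSPA5, IER3 and GATM among the falls. The sustained class held 57, 32 up and 25 down, with HMOX1, FTL, PIR, TXK and MAP1LC3B among the rises and GPR84, SGK1, CDC6, EGR1 and OAS3 among the falls. The late class held 45, 5 up and 40 down, with PLK1, AURKB, MKI67, CDC20 and TPX2 among the falls and INA among the rises. Without untreated replicate 2 the classes held 36, 91 and 74 clusters, and without untreated replicate 3 they held 1, 5 and 10. Without untreated replicate 1 they held 7, 348 and 41, without 8 h replicate 1 they held 0, 10 and 4, and without 8 h replicate 3 they held 0, 14 and 10. Without 24 h replicates 1, 2 and 3 they held 2, 15 and 10, then 0, 10 and 8, then 2, 14 and 13. The F-test called 43 without untreated replicate 3, 40, 188 and 52 without 8 h replicates 1, 2 and 3, and 74, 37 and 48 without 24 h replicates 1, 2 and 3. Both comparisons with 0 h shared the same 3 untreated arrays, so some overlap was built in. The untreated arrays also varied more than the others, which raises that overlap. The correlation of the changes across clusters was 0.715. In 100 simulations of unchanged groups it was 0.660 (0.636 to 0.683) with each group's own spread and 0.501 with the same spread in all groups. The covariance was 0.0511, against 0.0230 and 0.0156. At both times 32 clusters rose and 25 fell, where independent lists gave 0.49 and 0.57, and the simulations gave means of 0.45 and 0.36 with each group's own spread and 0 with the same spread. The simulated noise was independent between clusters and held no array that stood apart as untreated replicate 2 did. The simulated ranges may therefore be too narrow. Part of the excess may come from the shared untreated arrays. In both comparisons 0 clusters were called in opposite directions.

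In the fixed panel of NRF2-related genes, HMOX1 was called at both times, TXNRD1 at 8 h and GCLC at 24 h. Of the fits without 1 array, TXNRD1 at 8 h did not pass in 6 and GCLC at 24 h in 8. HMOX1 passed in all of them at both times. TXNRD1 at 24 h was 0.55 ± 0.11 above 0 h (adjusted p = 0.058), and its 3 arrays at 24 h shared the value 9.22. GCLC at 8 h was 0.77 ± 0.18 above 0 h (adjusted p = 0.10). GCLM, the modifier subunit of the same enzyme, was 0.73 ± 0.29 higher at 8 h (adjusted p = 0.30) and 0.80 ± 0.29 at 24 h (adjusted p = 0.20). SLC7A11, the cystine transporter, was 1.07 ± 0.23 higher at 8 h (adjusted p = 0.080) and 0.43 ± 0.23 at 24 h (adjusted p = 0.30). SRXN1, which repairs peroxiredoxins, was 0.35 ± 0.09 higher at 8 h (adjusted p = 0.14) and 0.24 ± 0.09 at 24 h (adjusted p = 0.21). KEAP1 was 0.27 ± 0.10 higher at 8 h (adjusted p = 0.27) and 0.32 ± 0.10 at 24 h (adjusted p = 0.16). RXRA, a nuclear receptor, differed by -0.17 ± 0.07 at 8 h (adjusted p = 0.33) and 0.12 ± 0.07 at 24 h (adjusted p = 0.38). None of these differences passed the test.

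Of 31 lists, 11 were called at 8 h against 0 h, 16 at 24 h against 0 h and 6 at 24 h against 8 h. With an estimated correlation the numbers were 0, 0 and 1. The fry test called 11, 10 and 4 lists for a movement in one direction. At 8 h these included NF-kB targets (fry adjusted p = 0.022) and fibroblast markers (0.036), but not the proteasome (0.54) or cholesterol (0.18) lists. Fibroblast markers were also called by fry at 24 h (adjusted p = 0.040). In 11 lists camera at the preset correlation called no comparison, with adjusted p from 0.059 to 0.92. These were metallothioneins, hypoxia and glycolysis, MYC and ribosome biogenesis, ribosomal proteins, histone deacetylases and DNA methyltransferases, B cell identity, plasma cell differentiation, MHC class II presentation, and the markers of T and NK cells, fibroblasts and epithelium. Of these, 5 were called without 1 array: hypoxia, MYC and MHC class II at 8 h without untreated replicate 2, T and NK cells at 8 h without 8 h replicate 2 and at 24 h without 24 h replicate 1, and plasma cell differentiation at 24 h without untreated replicate 3. Several uncalled lists were measured only in part. A cluster of their own was found for 4 of 10 metallothionein genes, 13 of 32 ribosomal proteins, 13 of 21 MYC genes and 7 of 12 MHC class II genes. The other members cannot be judged. Of the 33 list calls, 10 were lost without at least 1 array, 7 without the 25% of clusters with the lowest means, 8 without clusters below the median and 11 by directional fry. The sign of the mean, median or test differed in 16 of the 93 list tests, and 0 of those were called.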

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

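The tests of explanations for the lower mitosis genes were chosen after the result was seen, and the comparison with other splits of the arrays was chosen before it. The 8 h and 24 h groups were tested for a difference, in which exposure to sulforaphane and time in culture changed together, and 72 clusters passed. The 6 arrays of these groups make 10 splits, too few for a share below 0.05; 1 split, the real one, gave as many as 72 clusters, and the highest other gave 1. For the lists the real split gave 6 and the highest other 7, with 4 of the 10 splits at 6 or more.

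Mitotic genes were lower at 24 h than at 8 h: PLK1 by -1.42, CCNB2 by -1.27, CDC20 by -1.24, DLGAP5 by -1.22, MKI67 by -1.20 and TPX2 by -1.17. The mitosis list had a mean difference of -0.89, with 13 of 27 members called (adjusted p = 0.047 with an estimated correlation), and the histone list -0.31, with 0 of 29 called (adjusted p = 0.31 with an estimated correlation). Of 19 heat shock genes 4 were lower, HSPH1 at -0.75, HSP90AA1 at -0.64, STIP1 at -0.59 and BAG3 at -0.43, and the list had a mean of -0.30 (adjusted p = 0.24 with an estimated correlation). HMOX1 was lower by -0.69 and PHGDH by -0.50, the 1 called of 27 genes of the ATF4 list, which had a mean of -0.067 (adjusted p = 0.61 with an estimated correlation). Of 18 genes of the endoplasmic reticulum list 3 were higher at 24 h, HSPA5 by 0.62, MANF by 0.54 and HYOU1 by 0.38, with a list mean of 0.27 (adjusted p = 0.42 with an estimated correlation), and 0 passed without untreated replicate 3 or any 8 h or 24 h array. KCND2 was higher by 1.24, INA by 1.11, GATM by 0.80, DSG1 by 0.66, IER3 by 0.58, COQ10A by 0.58 and TM7SF2 by 0.40. The NF-kB list, with 1 of 18 members called, had a mean of 0.20 (adjusted p = 0.29 with an estimated correlation). Of the 22 called genes, 2 (without 8 h replicate 1) to 22 (without untreated replicate 2) passed when single arrays were left out, PLK1 and TPX2 in every fit, and the ATF4 list was not called without 8 h replicate 1.

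The mitosis genes were lower at 24 h than at 0 h by a mean of -0.85, with 18 of 27 members called and 9 not passed, and adjusted p = 7.1e-26 with the preset correlation but adjusted p = 0.25 with an estimated one (camera). The comparison of 24 h with 8 h uses no untreated array in its means and gave -0.89, which argues against untreated replicate 2 as the only source, and without that array the 24 h mean was -0.96. Scaling of the arrays is argued against as well, since the mean was -0.92 after centring each array and -0.95 after quantile normalization. Time in culture cannot be told apart from sulforaphane, since 0 arrays came from cells kept 8 or 24 h without it. An effect of sulforaphane on the cell cycle and a change in the growing culture both stay open.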

How the results depend on the processing

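The alternatives with clusters of at least 1 symbol, gene-by-gene array weights, clusters with 3 equal arrays left out, and both thresholds for single genes were chosen after seeing the data. Counts below are called clusters, in the order 8 h against 0 h, 24 h against 0 h and 24 h against 8 h where 3 are given (131, 357 and 72 as reported), then the F-test (298) and the early transient, sustained and late classes (11, 57 and 45). None of the 227 named gene results changed sign where called, and none of the list tests turned in direction against the other genes where called, but the mean of the called proteasome list at 8 h went from 0.064 to -0.016 without untreated replicate 2. Of 104 called gene results, 11 passed under every alternative that gave them a value, 14 under every such alternative except single arrays left out, and 93 were lost at least once; 22 passed the threshold of 0.01 and 81 the 1.5-fold minimum. The larger of rises and falls changed in 10 of 23 alternatives at 8 h, 14 of 23 at 24 h and 2 of 23 for 24 h against 8 h. Trended and robust eBayes and leaving out clusters with 3 equal arrays kept all these counts within 1.5 times. A block for the replicate number gave 85 at 8 h, 44 for 24 h against 8 h, 160 by the F-test and 6 early transient clusters, with 51 rises and 34 falls at 8 h (59 and 72 as reported) and 241 rises and 137 falls among 378 at 24 h (63.8% rises, 51.3% as reported); it called 253 of the 357 clusters at 24 h and 71 of the 104 called gene results. The labels give no pairing and 3 of 9 same-number pairs correlated above 0.1, up to 0.394 and 0.376 for 0 h with 24 h, against at most 0.134 for other numbers; 1 of 9 arrays correlated best with its own number in both other groups. Leaving out the 25% of clusters with the lowest means gave 302 at 8 h, 498 by the F-test, 22 early transient and 140 sustained. Leaving out clusters below the median gave 312 at 8 h, 115 for 24 h against 8 h, 482, 28 and 127. Clusters with at least 1 symbol gave 253 at 8 h, 120 for 24 h against 8 h, 451, 27 and 107, and averaged single symbols gave 215 at 8 h, 22 early transient and 93 sustained; these 4 alternatives test fewer clusters. Quantile normalization gave 390, 560 and 109, then 595, 20, 164 and 74. Median centring gave 288 at 8 h, 479 by the F-test and 135 sustained. Array weights gave 9603, 9010 and 1516, then 11791, 492, 5706 and 509, but their estimation did not converge and gave untreated replicate 3 a weight of 29.8 and untreated replicate 2 a weight of 0.136. Gene-by-gene weights gave 1703, 1889 and 1325, then 2912, 302, 705 and 412. A threshold of 0.01 gave 19, 24 and 19, then 40, 1, 10 and 10. A 1.5-fold minimum gave 80 at 8 h, 196 at 24 h, 6 early transient and 28 sustained. Fits of only the 2 groups compared, with fewer arrays and a spread from those 2 groups alone, gave 9, 20 and 25. They kept 8 of the 131, 20 of the 357 and 20 of the 72 calls. The reported fit used 1 spread for all groups, although the untreated arrays varied more. Its standard errors against 0 h may therefore be too small, and those of 24 h against 8 h too large. The counts of the 3 comparisons are thus not directly comparable. Of the called lists (11, 16 and 6), an estimated correlation left 0, 0 and 1; directional fry called 10 at 24 h, and mixed fry called 19 at 8 h and 12 for 24 h against 8 h. Leaving out single arrays gave 9 (untreated replicate 3) to 654 (untreated replicate 1) clusters at 8 h, 21 (untreated replicate 3) to 768 (untreated replicate 1) at 24 h, 4 (8 h replicate 1) to 160 (untreated replicate 2) for 24 h against 8 h, 37 (24 h replicate 2) to 430 (untreated replicates 1 and 2) by the F-test, 0 (8 h replicates 1 and 3, 24 h replicate 2) to 36 (untreated replicate 2) early transient, 5 (untreated replicate 3) to 348 (untreated replicate 1) sustained, 4 (8 h replicate 1) to 74 (untreated replicate 2) late, and 10 to 16, 12 to 16 and 5 to 9 called lists; a group left with 2 arrays took its spread from all groups. Leaving out an array outside a comparison did not change its means. Those calls moved only through the shared spread and the number of arrays behind it. Untreated replicates 1 and 2, which remain without replicate 3, correlated at 0.979, against 0.992 for 1 and 3 and 0.987 for 2 and 3. The cause of the other differences was not tested, also not for the smaller tests and fits named. Background signal was not analysed here, as the table holds no detection values.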

Other observations

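The tests of signal level and of a swap for untreated replicate 2, the Fisher tests and the median change of all clusters below the median signal were chosen after the result was seen; the other tests here were chosen before it. Some sustained genes outside the naming rule were picked after their values were seen. DUSP4, a phosphatase of MAP kinases, differed by -0.51 at 8 h and -0.58 at 24 h, and ETV4, an ETS transcription factor, by -0.74 and -0.69. PLAUR, the urokinase receptor, differed by -0.66 and -0.43, ALOX5, the enzyme that starts leukotriene synthesis, by -0.50 and -0.38, and CD93, a surface glycoprotein, by -0.66 at both times. TFE3, a transcription factor of lysosome genes, was higher by 0.57 and 0.44. Among late genes, FOXM1, a transcription factor of G2/M genes, differed by -0.99 at 24 h and -0.98 between 24 h and 8 h, and TSC22D3, a glucocorticoid-induced leucine zipper protein, was higher by 0.45 at 24 h. Their adjusted p-values from limma at 24 h were 0.014, 0.0084, 0.040, 0.030, 0.019, 0.037, 0.0076 and 0.014 in that order.

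Untreated replicate 2 stood apart, with a mean correlation of 0.977 to the other arrays. HMOX1 on it was 8.99, beside 8.77 and 9.03 on the other untreated arrays and at least 11.59 on the treated ones, which argues against a swap with a treated array. Its deviation from the other untreated arrays fell with signal across clusters (Spearman rho = -0.332, against 0.295 and 0.190 for untreated replicates 1 and 3). The deviations of the untreated arrays cancel out in each cluster, so these values are not independent. They cannot show by themselves to which array the trend belongs. A compressed signal on untreated replicate 2 may account for part of its distance, although clusters are not independent. RNA of other cells cannot be told apart from this: the highest of 4 marker lists, myeloid, reached percentile 89.45 of 10000 random lists of matched level, with T and NK, fibroblast and epithelial markers at 73.32, 66.47 and 74.47. The most abundant markers deviated by 0.37 for ELANE at a signal of 8.19, -0.68 for TRAT1 at 9.66, 0.12 for COL1A1 at 8.34 and 0.03 for KRT8 at 11.22, and 0 members of these lists are in another list. Of 15 T and NK, 11 myeloid, 10 fibroblast and 10 epithelial markers, 2, 1, 2 and 2 had a signal above the median of all clusters on the treated arrays.

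At 24 h, 71 of 183 risen clusters had a mean signal below the median of all clusters (38.8%), against 26 of 174 fallen ones (14.9%; Fisher's exact test, two-sided, p = 4.29e-07, with clusters not independent); at 8 h it was 18 of 59 against 19 of 72 (exact p = 0.697). A shift of all dim clusters is argued against by the median change of clusters below the median signal, -0.0426 at 24 h and -0.0408 at 8 h, and of the 25% with the lowest means, -0.0276 and -0.0255. Whether untreated replicate 2 was the only source cannot be told. Without it the median change of these risers was at least 0.947 of that with it, but they were selected with that array in the fit. Of the risers, 15 of 18 at 8 h and 34 of 71 at 24 h were still called. The share of dim clusters among rises and falls was not recounted without that array. Signal of neighbouring genes cannot be told apart from a response of the dim genes: the median change of adjacent genes was 0.286 of that of the risers at 24 h and 0.0871 at 8 h, and 30 of the 71 and 9 of the 18 had a place in the gene order. Of the adjacent genes, 3 of 18 at 8 h and 5 of 59 at 24 h were themselves called as rises. Among all 22011 clusters, 59 and 183 were. No biological explanation was tested.

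Other splits of the arrays were counted for each result. For 3 arrays against 3 there are 10 splits, too few for a share below 0.05; the real split gave 131 clusters at 8 h and the highest other 0, and 357 at 24 h and the highest other 0, with 1 split each giving as many. For the lists, the real split gave 11 at 8 h and the highest other 13, with 3 splits giving as many, and 16 at 24 h and the highest other 10, with 1 split giving as many. For the 3 groups, 100 of 280 splits were drawn, where a split ignores which group is 0, 8 or 24 h. Each was given 1 random order of the groups. A share below 0.05 was taken to argue against chance for the F-test, which does not depend on that order. The classes do depend on it, and other orders of the real groups were not drawn. Chance can therefore not be judged for the classes. The F-test gave 298 clusters against 25 in the highest other split (1 of 100), the sustained class 57 against 0 (1 of 100), the late class 45 against 10 (1 of 100) and the early transient class 11 against 19 (3 of 100).

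Equal values occurred on several arrays of the deposited table. In 893 clusters the 3 arrays of at least 1 group shared a value, 165 among untreated arrays, 438 at 8 h and 364 at 24 h, and 4982 clusters had 2 or 3 equal arrays in a group. Of the called clusters, 3 at 8 h, 4 at 24 h and 2 for 24 h against 8 h had 3 equal arrays in a group. Without such clusters, 124, 351 and 64 were called.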
